A study of Homo sapiens with 8 samples.

How the data were processed

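RNA labelled with 4-thiouridine was measured in MV4;11 cells in 4 groups of 2 libraries: DMSO (0.1%), I-BET151 (500 nM), SGC0946 (5 µM) and both compounds. Groups were taken from the sample labels. The submitters' processing notes name TopHat2, Bowtie2, HTSeq, edgeR and the build hg19 without versions or roles, and the library protocol was TruSeq; strandedness is not given in the sources used here. The deposited table of 16684 Ensembl genes holds a signal made by the authors: CPM computed on normalized library sizes. The design expected plain CPM, but its column totals ran from 884200 to 1265202, so the unit is called signal. The planned limma test on the logarithm of the values was kept. Because the values are relative, a global rise or fall of RNA output cannot be measured.

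Whole reads were recovered from the spacing of the values in each library, with 100% of values within 0.05 of a whole read. TMM factors from edgeR (0.79 to 1.13) gave the deposited values back to within 8.7e-07 percent. Depth was 13635585 to 18401438 reads per library, and the median gene had 122 to 165 reads. A single Ensembl gene without a symbol in the tables used here took 31.1 to 39.6% of reads, and the 4 most abundant features, which include both mitochondrial ribosomal RNAs, took 57 to 68.5%, the highest share being in combination replicate 2. Symbols came from a gene name table for 14655 genes and from GENCODE release 29 for 1344, while 685 genes had none. That reference uses a later genome build than the deposited files, so no coordinates are given.

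Changes were tested with limma 3.58.1 (linear fit, contrasts, empirical Bayes with an intensity trend) on log2 of the value plus 0.5, in 1 fit of all 8 libraries with 4 residual degrees of freedom. Genes needed a value of at least 1 in at least 2 libraries, which removed 0 genes. Benjamini-Hochberg adjustment was made per comparison and the threshold was 0.05. The 7 comparisons were each treatment against DMSO, the combination against each single compound, I-BET against SGC0946, and the interaction. Comparisons, tests, the naming rule and gene lists were fixed before the data were examined. The rule named the 8 higher and 8 lower genes with the largest fold changes against DMSO, and 5 and 5 elsewhere, among genes past the threshold with a mean of at least 5 in either group and replicates that did not overlap between groups. It also named a fixed set of genes whatever their result, some of which are not reported, and up to 2 highest and 2 lowest members of each list; CD14 was not analysed here. The text leaves out some genes the rule named, mostly those whose call ended without a library or with few reads in a group.

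Gene lists were tested with limma camera at a preset inter-gene correlation of 0.01, adjusted over 140 tests. Of 25 lists written from general knowledge, 20 had at least 5 tested members. Correlations across genes carry no p-value; the value from shared controls was taken from 100 simulations of unchanged groups. Alternatives were pseudocounts of 0.1 and 2, no filter, a mean of at least 5, median-of-ratios and upper-quartile scaling, no intensity trend, only the groups compared, a replicate block, each library left out, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, camera with an estimated correlation, and fry. List tests and list counts without each library, and a split of the DMSO libraries between I-BET and SGC0946, were added after seeing the data. The common dispersion in edgeR was 0.00833, a biological coefficient of variation of 9.1%.

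The tests were tested on simulated data with 16684 genes. For I-BET against DMSO, limma found 35.8% of 67 genes changed 1.5-fold, 91% of 67 changed 2-fold and 98.5% of 66 changed 4-fold, and 5.7% of its calls were unchanged genes. For the interaction it found 16.4%, 47.8% and 90.9%, and 4.6% of its calls were unchanged genes. Each simulation was 1 run in which only these 67, 67 and 66 genes changed, equally up and down. The dispersion of each gene was set by the trend alone. In the real I-BET comparison limma called 4670 genes, so these shares may not hold there. A simulated list of 30 genes shifted by 0.5 log2 units had a camera adjusted p of 8.1e-46 with the preset and 0.0027 with the estimated correlation, and 0 of 20 unshifted lists were called. Simulated genes were drawn independently of each other, so false list calls from correlation between genes could not arise. The preset correlation was therefore not tested against them. Of 199 genes the rule named, 46 share exonic sequence with another gene of the deposited table in GENCODE release 29. The largest shares were in TUBB1 and CCNE2, and overlaps with genes outside the table were not counted. Computation used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3.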

Results

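Newly made RNA was measured in the human MV4;11 leukaemia line after treatment with DMSO, the BET bromodomain inhibitor I-BET151 at 500 nM (I-BET), the DOT1L inhibitor SGC0946 at 5 µM, or both compounds together (combination). RNA was labelled with 200 µM 4-thiouridine during the last 60 min of treatment. The treatment time before that is not given in the sources used here. Each of the 4 groups had 2 libraries, with 13635585 to 18401438 recovered reads per library, and 16684 genes were tested. Values are in the deposited unit, a CPM on normalized library sizes, and changes are log2 fold changes ± SE with n = 2 libraries per group. All p-values measure only the spread between these samples, because the labels do not say whether replicates were separate cultures. Within-group correlations of log2 values ran from 0.988 to 0.989, and between-group correlations from 0.941 to 0.984.

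What did BET inhibition alone do to newly made RNA? With I-BET, RNA of the oncogene MYC fell from 799 ± 138 in DMSO to 257 ± 14.7 (mean ± SD, n = 2), a change of -1.62 ± 0.20 (limma adjusted p = 2.9e-05). The anti-apoptotic gene BCL2 changed by -1.35 ± 0.10 (limma adjusted p = 5.2e-07), and the G1 kinase gene CDK6 by -1.27 ± 0.16 (limma adjusted p = 3.5e-05). HEXIM1, whose product holds the elongation kinase P-TEFb inactive, rose by 1.74 ± 0.11 (limma adjusted p = 2.0e-07). In all these genes both I-BET libraries lay on the same side of both DMSO libraries.

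The largest rises after I-BET were in RGS2 (2.84 ± 0.29), a regulator of G-protein signalling, SAT1 (2.64 ± 0.19), which acetylates polyamines, FAM222A (2.36 ± 0.19), the kinase gene SGK1 (2.33 ± 0.27), FGD6 (2.11 ± 0.19), SERTAD1 (2.03 ± 0.17), the metallothionein gene MT2A (2.01 ± 0.20) and PLXNA3 (1.96 ± 0.15). The largest falls were in OCSTAMP (-4.35 ± 0.25), which acts in osteoclast fusion, the chemokine receptor gene CCR2 (-3.62 ± 0.33), MYBPH (-2.97 ± 0.29), TCF23 (-2.86 ± 0.24), LGALS12 (-2.80 ± 0.18), the macrophage pore-protein gene MPEG1 (-2.72 ± 0.31), DLX1 (-2.53 ± 0.26) and CSPG4 (-2.51 ± 0.21). Limma adjusted p for these 16 genes ran from 1.8e-07 for OCSTAMP to 1.8e-05 for SGK1. In all, limma called 4670 genes, 1969 higher and 2701 lower, and 878 of them changed at least 2-fold. edgeR called 4663 genes and DESeq2 3125. Limma called 1065 higher and 1919 lower without DMSO replicate 2, 1178 and 2086 without I-BET replicate 1, and 1194 and 1807 without I-BET replicate 2. The 878 became 429 with a pseudocount of 2.

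The homeobox gene HOXA10 rose with I-BET by 0.68 ± 0.14 (limma adjusted p = 0.00161). HOXA9 rose by 0.50 ± 0.11 (limma adjusted p = 0.00312), a call that ended without DMSO replicate 2 (0.40, adjusted p = 0.0563). The receptor kinase gene FLT3 changed by -0.43 ± 0.12 (limma adjusted p = 0.0124), lost without DMSO replicate 1 (adjusted p = 0.1) or I-BET replicate 2 (adjusted p = 0.0993). BRD2, itself a BET gene, rose by 0.52 ± 0.12 (limma adjusted p = 0.0041), lost without DMSO replicate 2 (adjusted p = 0.0833). DOT1L changed by -0.32 ± 0.11 (limma adjusted p = 0.0409), lost without DMSO replicate 1 (0.195), DMSO replicate 2 (0.0975) or I-BET replicate 2 (0.359). MEIS1 (0.22 ± 0.11), PBX3 (-0.21 ± 0.11), MEF2C (-0.14 ± 0.12), MYB (-0.11 ± 0.12) and the monocyte integrin gene ITGAM (0.39 ± 0.28) did not pass the test, with limma adjusted p from 0.16 to 0.512. Of 17 MLL fusion targets, 2 were higher, 6 lower and 9 not past the threshold, also 2 and 6 when adjusted over the list alone (limma camera adjusted p = 0.123; adjusted p = 0.706 with an estimated correlation). Without DMSO replicate 2, 1 was higher and 5 lower.

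Most genes of the MYC and ribosome biogenesis list and of the granule list fell with I-BET, while those of the histone list rose. Of 39 genes of MYC and ribosome biogenesis, 0 were higher, 36 lower and 3 not past the threshold, and 37 were lower when adjusted over the list alone (median -0.94, limma camera adjusted p = 8.9e-22; adjusted p = 0.301 with an estimated correlation). The folate carrier gene SLC19A1 in that list changed by -1.82 ± 0.15. All 16 tested genes of the list of histones with polyadenylated or replication-independent transcripts were higher, also 16 when adjusted over the list alone. That list had a median of 0.98 (limma camera adjusted p = 3.8e-11, adjusted p = 0.333 with an estimated correlation). H4C8 rose by 1.28 ± 0.17 (limma adjusted p = 6.6e-05), although near-identical histone genes can share reads. All 9 granule genes of myeloid progenitors were lower, also 9 when adjusted over the list alone (median -1.21, limma camera adjusted p = 3.3e-07; adjusted p = 0.301 with an estimated correlation). Among them the protease gene CTSG changed by -1.67 ± 0.19, and RNASE2, whose reads RNASE3 may share, by -1.30 ± 0.14. The macrophage growth-factor receptor gene CSF1R (-1.80 ± 0.23, limma adjusted p = 4.5e-05) and the progenitor factor gene GATA2 (-1.81 ± 0.23, limma adjusted p = 4.2e-05) also fell.

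The other lists called after I-BET had a smaller share of members past the threshold. Of 26 haematopoietic transcription factor genes, 2 were higher, 10 lower and 14 not past the threshold, with 2 higher and 13 lower when adjusted over the list alone (limma camera adjusted p = 0.00273; adjusted p = 0.55 with an estimated correlation). There were 4 higher and 9 lower without DMSO replicate 1, and 1 higher without DMSO replicate 2, I-BET replicate 1 or either combination replicate. Of 83 ribosomal protein genes, 6 were lower and 77 not past the threshold, with 0 when adjusted over the list alone (median -0.21, limma camera adjusted p = 7.8e-04; adjusted p = 0.829 with an estimated correlation). That 6 became 1 without DMSO replicate 1, 0 without DMSO replicate 2, 1 without I-BET replicate 1, 2 without I-BET replicate 2 and 12 without either SGC0946 replicate. Of 13 mitochondrially encoded genes, 2 were lower and 11 not past the threshold, with 0 when adjusted over the list alone (limma camera adjusted p = 0.0431; adjusted p = 0.753 with an estimated correlation). That mitochondrial result ended without DMSO replicate 1 (0 lower, 0.121), DMSO replicate 2 (0 lower, 0.0987), I-BET replicate 1 (0 lower, 0.062) or I-BET replicate 2 (0 lower, 0.166). Limma camera adjusted p ran from 0.0518 to 0.923 for the lists of DOT1L and elongation complexes, BET proteins and P-TEFb control, cell cycle, CDK inhibitors and p53 targets, BCL2 family, monocyte markers, immediate early genes, NF-kB and cytokines, interferon response, cholesterol synthesis, heat shock and unfolded protein response, MHC class II, and snoRNA hosts. Some of these lists passed limma camera at the preset correlation when a library was left out. Ranked upward were immediate early genes without DMSO replicate 1 (1.1e-04) or I-BET replicate 2 (0.0187), CDK inhibitors and p53 targets without DMSO replicate 1 (0.0269), and BET proteins and P-TEFb control without DMSO replicate 1 (0.0371) or I-BET replicate 1 (0.0451). Ranked downward were monocyte markers without DMSO replicate 2 (0.00161) or I-BET replicate 1 (0.0147), NF-kB and cytokines without DMSO replicate 2 (0.0146) or I-BET replicate 1 (0.0187), MHC class II without DMSO replicate 2 (0.021), snoRNA hosts without I-BET replicate 2 (0.0131) and cholesterol synthesis without DMSO replicate 1 (0.0449). In the heat shock list the median (-0.03) and mean (-0.02) were negative while camera ranked the list upward.

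What did DOT1L inhibition alone change? SGC0946 lowered RNA of the MLL-fusion target genes HOXA9 (-1.05 ± 0.11, limma adjusted p = 5.9e-05), HOXA10 (-0.94 ± 0.14, limma adjusted p = 7.3e-04), PBX3 (-1.18 ± 0.11, limma adjusted p = 1.6e-05), MEF2C (-1.13 ± 0.12, limma adjusted p = 1.0e-04) and FLT3 (-0.95 ± 0.12, limma adjusted p = 2.6e-04). HOXA9 stood at 71.7 ± 7.07 in DMSO and 34.4 ± 0.836 with SGC0946 (mean ± SD, n = 2). MEIS1, the partner of HOXA9, changed by -0.54 ± 0.11 (limma adjusted p = 0.0112), lost without DMSO replicate 1 (0.0513), DMSO replicate 2 (0.0939) or SGC0946 replicate 1 (0.114). MYC (0.42 ± 0.20), BCL2 (-0.27 ± 0.10), CDK6 (-0.48 ± 0.16), MYB (-0.20 ± 0.12), HEXIM1 (-0.17 ± 0.11), BRD2 (-0.20 ± 0.12), DOT1L (-0.33 ± 0.11) and ITGAM (0.96 ± 0.28) did not pass, with limma adjusted p from 0.0596 to 0.454. Of these, ITGAM passed without DMSO replicate 1 (1.39, limma adjusted p = 0.0153) and CDK6 without I-BET replicate 1 or 2 (limma adjusted p = 0.0496 and 0.0495).

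The largest rises after SGC0946 were in GAPT (3.49 ± 0.26), the serpin gene SERPINB2 (2.97 ± 0.33), SAMSN1 (2.77 ± 0.29), ARID5B (2.52 ± 0.19), TENT5A (2.50 ± 0.15), the pioneer factor gene FOXA1 (2.49 ± 0.22), STARD13 (2.33 ± 0.21) and PRDM1 (2.25 ± 0.18), which encodes a transcriptional repressor. GAPT and SERPINB2 started from 12 and 7 reads over both DMSO libraries. The falls whose calls held without any library were OCSTAMP (-3.42 ± 0.25), the low-affinity IgE receptor gene FCER2 (-2.06 ± 0.24), the stress pseudokinase gene TRIB3 (-1.62 ± 0.28), ATF5 (-1.55 ± 0.16) and ARID3B (-1.33 ± 0.11). Limma adjusted p for these 13 genes ran from 7.4e-07 for TENT5A to 0.00287 for TRIB3. TRIB3 stood at 93.61 and 40.16 in DMSO replicates 1 and 2, and at 21.06 and 18.38 with SGC0946. The size of its fall therefore depended on DMSO replicate 1. KLF2 (-1.91 ± 0.51), EGR1 (-1.81 ± 0.48) and PLEKHF1 (-1.29 ± 0.33) passed, but without DMSO replicate 1 they stood at -0.84, -0.65 and -0.95 (limma adjusted p = 0.372, 0.306 and 0.25). They were also lost without either SGC0946 replicate (KLF2 0.127 and 0.219, EGR1 0.144 and 0.205, PLEKHF1 0.0878 and 0.228) or either combination replicate (KLF2 0.0676 and 0.0675, EGR1 0.0673 and 0.0673, PLEKHF1 0.0572 and 0.057). Limma called 825 genes, 409 higher and 416 lower, with 199 changed at least 2-fold, and edgeR called 933 and DESeq2 583. The balance turned with single libraries: 263 higher and 134 lower without DMSO replicate 1, 192 and 272 without DMSO replicate 2, 141 and 179 without SGC0946 replicate 1, and 226 and 152 without SGC0946 replicate 2. The 199 became 131 without SGC0946 replicate 1 and 90 with a pseudocount of 2.

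With SGC0946 the MLL fusion target list leaned lower and the MHC class II list higher. Of 17 MLL fusion targets, 0 were higher, 8 lower and 9 not past the threshold, with 11 lower when adjusted over the list alone (median -0.47, limma camera adjusted p = 1.3e-13; adjusted p = 0.301 with an estimated correlation). The count was 5 without DMSO replicate 2 or SGC0946 replicate 1. Of 14 MHC class II and antigen presentation genes, 6 were higher and 8 not past the threshold, with 8 higher when adjusted over the list alone (median 0.36, limma camera adjusted p = 4.7e-08; adjusted p = 0.357 with an estimated correlation). Without SGC0946 replicate 1, 3 were higher. HLA-DRA rose by 2.17 ± 0.35 (limma adjusted p = 0.00188) and HLA-DQB1 by 1.67 ± 0.27 (limma adjusted p = 0.00159), although related HLA genes can share reads. Of 9 granule genes, 4 were higher and 5 not past the threshold, also 4 when adjusted over the list alone (limma camera adjusted p = 1.7e-04; adjusted p = 0.332 with an estimated correlation). Among them the myeloperoxidase gene MPO rose by 1.23 ± 0.21 (limma adjusted p = 0.0027) and MS4A3 by 1.02 ± 0.15 (limma adjusted p = 8.1e-04). The lysozyme gene LYZ, from the monocyte marker list, rose by 1.61 ± 0.20 (limma adjusted p = 2.6e-04).

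The cholesterol synthesis list leaned lower after SGC0946. Of 21 cholesterol synthesis genes, 9 were lower and 12 not past the threshold, with 14 lower when adjusted over the list alone (median -0.46, limma camera adjusted p = 6.0e-11; adjusted p = 0.301 with an estimated correlation). The 9 became 0 without DMSO replicate 2, 2 without SGC0946 replicate 1 and 4 without SGC0946 replicate 2. Of 22 heat shock and unfolded protein response genes, 1 was higher, 6 lower and 15 not past the threshold, with 1 higher and 12 lower when adjusted over the list alone (limma camera adjusted p = 1.7e-07; adjusted p = 0.301 with an estimated correlation). Those 6 became 2 without DMSO replicate 1 or either SGC0946 replicate, and 3 without either combination replicate, and 0 were higher without either DMSO or SGC0946 replicate. Of 25 immediate early genes, 1 was higher, 8 lower and 16 not past the threshold, with 1 higher and 12 lower when adjusted over the list alone (limma camera adjusted p = 1.1e-08; adjusted p = 0.56 with an estimated correlation). Those 8 became 2 without DMSO replicate 1, 17 without DMSO replicate 2, 3 without either SGC0946 replicate and 5 without either combination replicate, and the 1 higher gene became 0 without DMSO replicate 2 or SGC0946 replicate 1. Of 23 CDK inhibitor and p53 target genes, 0 were higher, 4 lower and 19 not past the threshold, with 1 higher and 4 lower when adjusted over the list alone (limma camera adjusted p = 3.5e-04; adjusted p = 0.332 with an estimated correlation). Those 4 became 1 without DMSO replicate 1 and 2 without either SGC0946 replicate, while CDKN1A, the cell-cycle inhibitor p21, changed by -1.09 ± 0.14 (limma adjusted p = 3.0e-04).

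Several SGC0946 list results were small or ended without a library. Of 26 haematopoietic transcription factor genes, 1 was higher and 5 lower (2 and 8 when adjusted over the list alone; limma camera adjusted p = 0.0106; adjusted p = 0.606 with an estimated correlation), with 2 higher and 1 lower without DMSO replicate 1 (0.241) and 2 lower without either SGC0946 replicate. In that list BCL6, a transcriptional repressor, rose by 2.00 ± 0.20 (limma adjusted p = 3.6e-05). Cell cycle genes leaned lower (1 of 36 lower; limma camera adjusted p = 6.4e-04; adjusted p = 0.753 with an estimated correlation), which ended without DMSO replicate 1 (0 lower, 0.163) or SGC0946 replicate 1 (0 lower, 0.268). Without SGC0946 replicate 2, 0 were lower. The BET and P-TEFb list also leaned lower (1 of 12 lower; limma camera adjusted p = 0.0306; adjusted p = 0.334 with an estimated correlation), which ended without DMSO replicate 1 (0 lower, 0.117) or SGC0946 replicate 1 (0 lower, 0.184). Its count was 0 lower without DMSO replicate 2, I-BET replicate 2 or SGC0946 replicate 2. No member passed in the lists of histones (limma camera adjusted p = 0.0216; adjusted p = 0.753 with an estimated correlation), mitochondrially encoded genes (limma camera adjusted p = 0.00659; adjusted p = 0.706 with an estimated correlation) or ribosomal proteins (limma camera adjusted p = 0.0283; adjusted p = 0.924 with an estimated correlation). The histone result ended without DMSO replicate 1 (0.88) or SGC0946 replicate 2 (0.268). The ribosomal protein result ended without DMSO replicate 1 (0.362) and took the opposite direction without SGC0946 replicate 1 (1.4e-04), and 1 member was higher without SGC0946 replicate 2. The MYC and ribosome biogenesis list, with 0 of 39 genes past the threshold and a median of 0.03, and the lists of DOT1L and elongation complexes, BCL2 family, NF-kB and cytokines, interferon response and snoRNA hosts had limma camera adjusted p from 0.0647 to 0.814. Of these, NF-kB and cytokines passed downward without DMSO replicate 2 (0.00115), and snoRNA hosts upward without DMSO replicate 2 (0.0297) or SGC0946 replicate 2 (0.0271). Of 18 monocyte marker genes, 6 were higher and 1 lower, or 7 and 2 when adjusted over the list alone (limma camera adjusted p = 0.0512; adjusted p = 0.753 with an estimated correlation). That list passed upward without DMSO replicate 1 (4.1e-04), SGC0946 replicate 2 (0.0012), I-BET replicate 1 (0.0467) or I-BET replicate 2 (0.0443). Its 6 became 1 without DMSO replicate 2 or SGC0946 replicate 1, and its 1 became 0 without DMSO replicate 1 or either SGC0946 replicate.

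**Figure D1:**
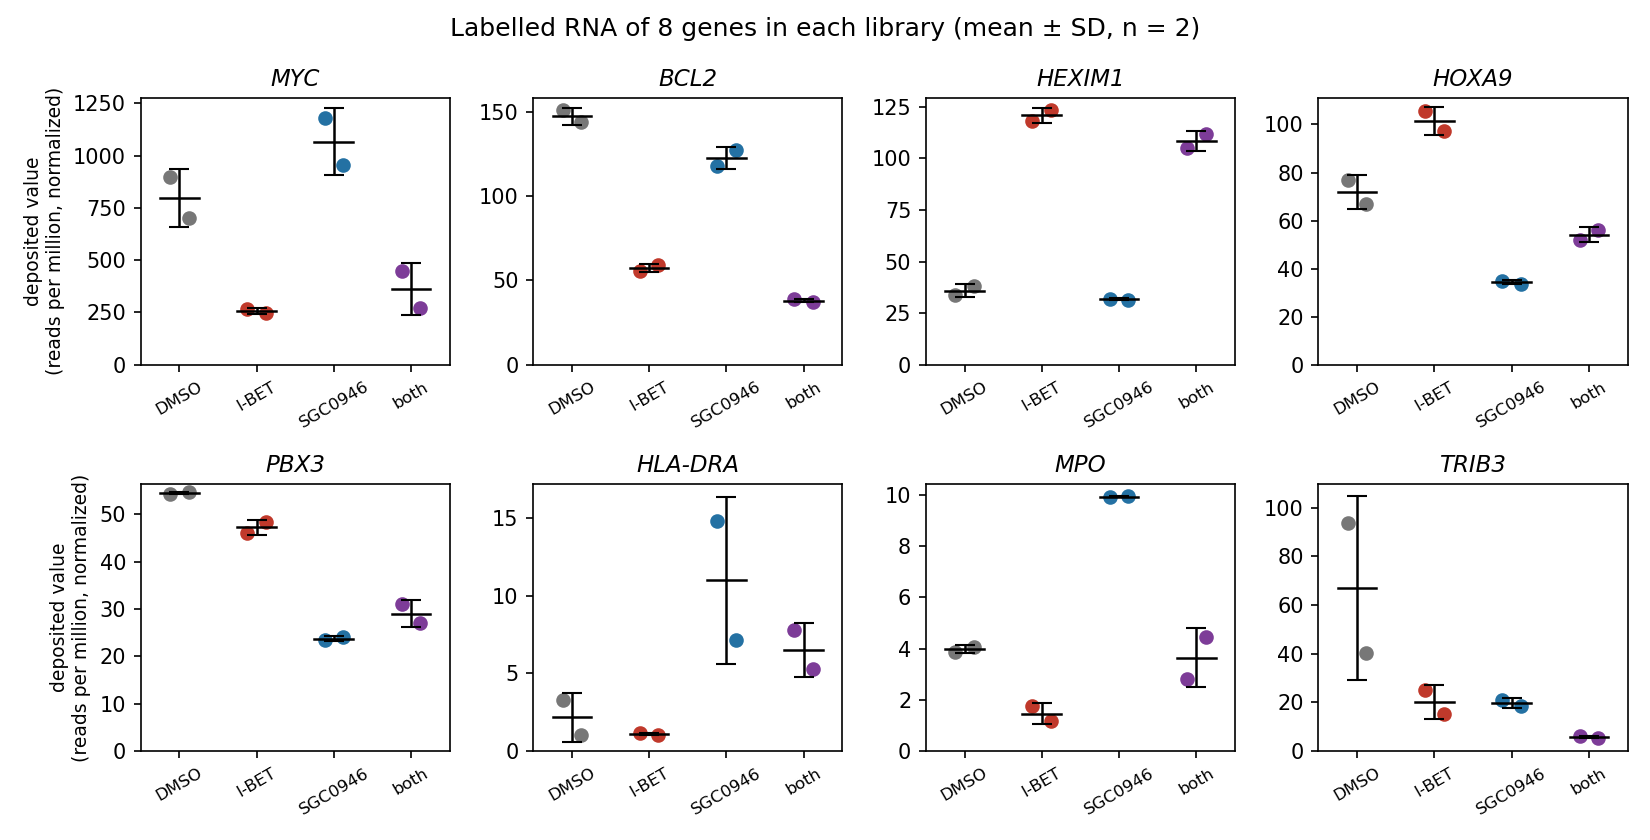
Deposited value (y axis, CPM on normalized library sizes) of MYC, BCL2, HEXIM1, HOXA9, PBX3, HLA-DRA, MPO and TRIB3 in the 4 groups (x axis). Points are libraries and bars are mean ± SD (n = 2 per group); HEXIM1 averaged 35.8 in DMSO and 121 with I-BET.

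What was the state under both compounds? In the combination MYC changed by -1.18 ± 0.20 (limma adjusted p = 3.8e-04), BCL2 by -1.94 ± 0.10 (limma adjusted p = 9.8e-09) and CDK6 by -1.19 ± 0.16 (limma adjusted p = 4.8e-05) against DMSO, and HEXIM1 rose by 1.59 ± 0.11 (limma adjusted p = 8.6e-08). PBX3 (-0.90 ± 0.11, limma adjusted p = 2.1e-05), MEF2C (-0.99 ± 0.12, limma adjusted p = 3.0e-05), FLT3 (-0.91 ± 0.12, limma adjusted p = 3.8e-05) and DOT1L (-0.46 ± 0.11, limma adjusted p = 0.00524) also fell. HOXA9 changed by -0.40 ± 0.11 (limma adjusted p = 0.0116), lost without DMSO replicate 1 (0.138) or combination replicate 1 (0.0808). MYB (-0.33 ± 0.12, limma adjusted p = 0.0455) was lost without either DMSO, I-BET or combination replicate, with a highest adjusted p of 0.294 without DMSO replicate 1. ITGAM (0.91 ± 0.28, limma adjusted p = 0.0216) was lost without DMSO replicate 2 (0.275), combination replicate 1 (0.069) or combination replicate 2 (0.115). HOXA10 (-0.31 ± 0.14), MEIS1 (-0.28 ± 0.11) and BRD2 (0.27 ± 0.12) did not pass, with limma adjusted p from 0.0832 to 0.109, though HOXA10 did without combination replicate 1 (-0.47, limma adjusted p = 0.0418).

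The largest rises in the combination were in the arrestin-like gene ARRDC3 (3.03 ± 0.27), RGS2 (2.99 ± 0.29), DPYSL3 (2.58 ± 0.18), the stress-response gene SESN3 (2.52 ± 0.13), FAM222A (2.42 ± 0.19), SAT1 (2.42 ± 0.19), RTL5 (2.33 ± 0.22) and CAPN5 (2.32 ± 0.25). The largest falls were in CSPG4 (-3.72 ± 0.21), the activin subunit gene INHBA (-3.47 ± 0.18), TRIB3 (-3.31 ± 0.28), CCR2 (-3.31 ± 0.33), FCER2 (-3.23 ± 0.24), LGALS12 (-3.16 ± 0.18) and MYBPH (-3.09 ± 0.29), and OCSTAMP went from 1123 reads in DMSO to 0 in both combination libraries. Limma adjusted p for the 15 genes with a fold ran from 9.1e-09 for SESN3 to 7.0e-06 for CAPN5. The myeloid master regulator gene SPI1 changed by -1.70 ± 0.15 (limma adjusted p = 9.4e-07). Limma called 4869 genes, 2165 higher and 2704 lower, with 991 changed at least 2-fold, and edgeR called 4868 and DESeq2 3448. Limma called 1262 higher and 1976 lower without DMSO replicate 2, and 1368 and 2052 without combination replicate 2. The 991 became 508 with a pseudocount of 2.

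In the combination most genes of MYC and ribosome biogenesis were lower than in DMSO and most genes of the histone list higher. Of 39 MYC and ribosome biogenesis genes, 34 were lower and 5 not past the threshold, with 36 lower when adjusted over the list alone (median -0.71, limma camera adjusted p = 2.1e-16; adjusted p = 0.328 with an estimated correlation). Of 16 histone genes, 15 were higher and 1 not past the threshold, also 15 when adjusted over the list alone (median 0.79, limma camera adjusted p = 1.1e-08; adjusted p = 0.378 with an estimated correlation). Of 17 MLL fusion targets, 10 were lower and 7 not past the threshold, with 11 lower when adjusted over the list alone (median -0.40, limma camera adjusted p = 5.8e-07; adjusted p = 0.301 with an estimated correlation). Of 21 cholesterol synthesis genes, 1 was higher, 13 lower and 7 not past the threshold, with 1 and 14 when adjusted over the list alone (limma camera adjusted p = 4.7e-06; adjusted p = 0.357 with an estimated correlation). The sterol oxidase gene MSMO1 changed by -1.31 ± 0.15 (limma adjusted p = 1.6e-05). Of 26 haematopoietic transcription factor genes, 1 was higher and 15 lower, the same when adjusted over the list alone (limma camera adjusted p = 1.3e-05; adjusted p = 0.364 with an estimated correlation), with 3 higher and 13 lower without DMSO replicate 1. Of 9 granule genes, 0 were higher and 4 lower, with 1 higher and 6 lower when adjusted over the list alone (limma camera adjusted p = 0.00852; adjusted p = 0.461 with an estimated correlation). Among these, 1 was higher without DMSO replicate 2 or either I-BET replicate.

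Further combination results depended on single libraries. Of 22 heat shock and unfolded protein response genes, 3 were higher, 10 lower and 9 not past the threshold, with 4 and 10 when adjusted over the list alone (limma camera adjusted p = 0.0259; adjusted p = 0.595 with an estimated correlation). That list ended without DMSO replicate 1 (3 higher, 6 lower, 0.0537), and it had 2 higher and 6 lower without combination replicate 1. Of 14 MHC class II and antigen presentation genes, 7 were higher, 2 lower and 5 not past the threshold, the same when adjusted over the list alone (limma camera adjusted p = 0.0461; adjusted p = 0.753 with an estimated correlation). That list ended without DMSO replicate 2 (1 higher, 0 lower, 0.107), combination replicate 1 (4 higher, 0 lower, 0.0512) or combination replicate 2 (3 higher, 1 lower, 0.0635). In it, 1 was lower without DMSO replicate 1. Of 83 ribosomal protein genes, 1 was higher and 2 lower, with 0 when adjusted over the list alone (median 0.17, limma camera adjusted p = 0.00525; adjusted p = 0.865 with an estimated correlation). That list ended without DMSO replicate 1 (0 higher, 1 lower, 0.0642) or combination replicate 2 (0 higher, 0 lower, 0.244), and 10 were higher without either SGC0946 replicate. It had 0 higher and 1 lower without DMSO replicate 2, and 0 higher without either I-BET replicate. The lists of DOT1L and elongation complexes, BET proteins and P-TEFb control, cell cycle, CDK inhibitors and p53 targets, BCL2 family, monocyte markers, immediate early genes, NF-kB and cytokines, interferon response, mitochondrially encoded genes and snoRNA hosts had limma camera adjusted p from 0.0714 to 0.942. Without DMSO replicate 2, limma camera at the preset correlation ranked downward immediate early genes (2.8e-06), NF-kB and cytokines (0.00112), the BCL2 family (0.0144) and monocyte markers (0.0224). It also did so for NF-kB and cytokines without I-BET replicate 1 (0.0483), I-BET replicate 2 (0.0449) or combination replicate 1 (0.0486), and for mitochondrially encoded genes without combination replicate 2 (0.028). In the interferon list the median (-0.05) and mean (-0.01) were negative while camera ranked the list upward.

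**Figure D2:**
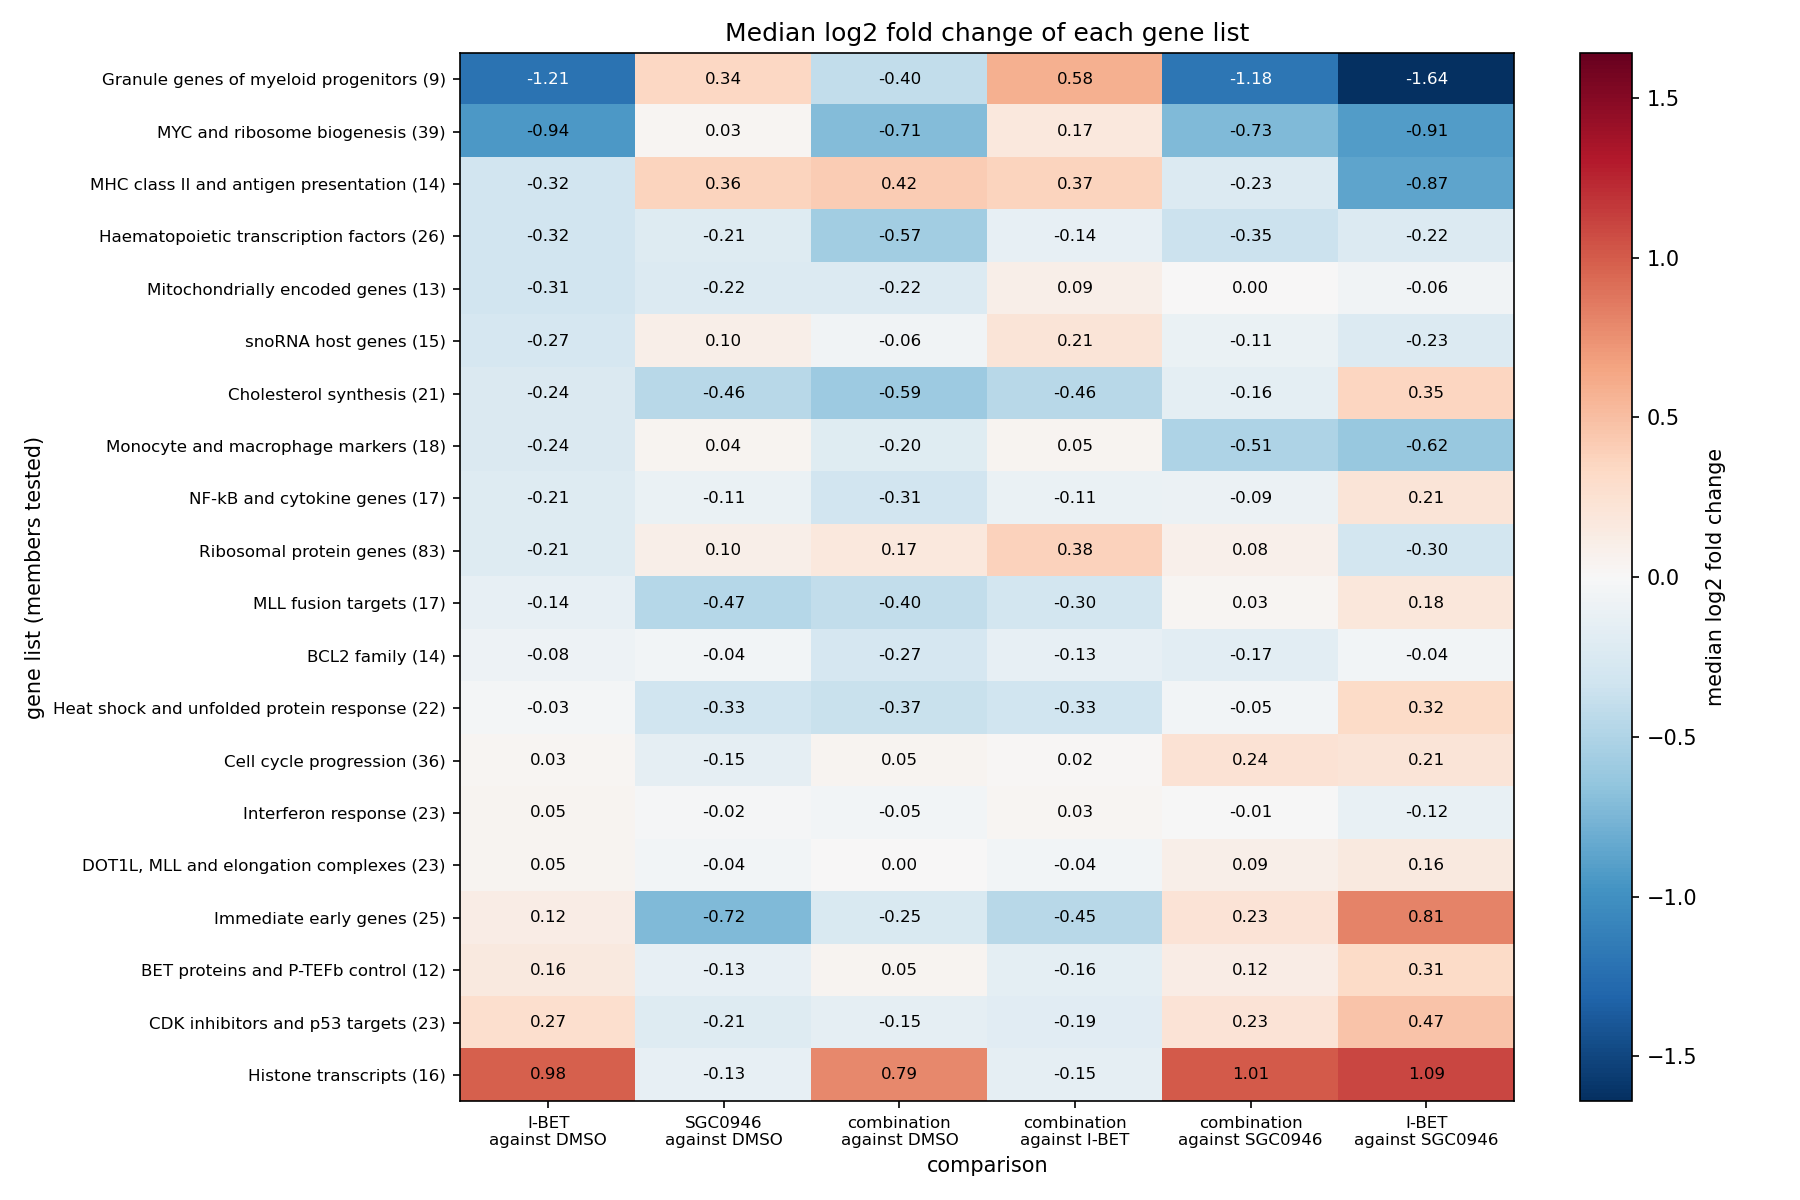
Median log2 fold change over the tested members of 20 gene lists (y axis) in 6 comparisons (x axis), with colour for direction and size, from n = 2 libraries per group. The histone list had a median of 0.98 and the MYC and ribosome biogenesis list -0.94 after I-BET; no error bars are drawn.

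What did adding SGC0946 to I-BET change? Against I-BET alone, the combination lowered HOXA9 (-0.90 ± 0.11, limma adjusted p = 5.9e-04), HOXA10 (-0.98 ± 0.14, limma adjusted p = 0.00142) and MEF2C (-0.85 ± 0.12, limma adjusted p = 0.00201). PBX3 (-0.70 ± 0.11, limma adjusted p = 0.00304) was lost without combination replicate 2 (0.0524), and BCL2 (-0.59 ± 0.10, limma adjusted p = 0.00611) without I-BET replicate 2 (0.07) or combination replicate 2 (0.0657). MYC (0.44 ± 0.20, limma adjusted p = 0.296) and HEXIM1 (-0.16 ± 0.11, limma adjusted p = 0.523) did not pass. PRDM1 rose by 2.41 ± 0.18 (limma adjusted p = 1.2e-05), the matrix metalloprotease gene MMP2 by 2.15 ± 0.23 (limma adjusted p = 2.2e-04), CES1 by 1.92 ± 0.24 (limma adjusted p = 7.8e-04) and ARID5B by 1.92 ± 0.19 (limma adjusted p = 2.2e-04). The potassium channel gene KCNN2 changed by -1.49 ± 0.16 (limma adjusted p = 2.2e-04), CDKN1A by -1.19 ± 0.14 (limma adjusted p = 5.1e-04) and the Fc receptor gene FCGR1A by -1.35 ± 0.19 (limma adjusted p = 0.00175). HLA-DRA rose by 2.12 ± 0.35 (limma adjusted p = 0.00421), lost without combination replicate 1 (0.0736), and its partner CD74 by 1.28 ± 0.14 (limma adjusted p = 3.9e-04). Limma called 471 genes, 245 higher and 226 lower, with 97 changed at least 2-fold, and edgeR called 419 and DESeq2 317. The balance turned with single libraries: 128 higher and 52 lower without I-BET replicate 1, 69 and 122 without I-BET replicate 2, 70 and 101 without combination replicate 1, and 58 and 46 without combination replicate 2. The 97 became 54 without combination replicate 2 and 32 with a pseudocount of 2.

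On an I-BET background the MLL fusion target and cholesterol synthesis lists leaned lower with SGC0946, and the MHC class II and granule lists higher. Of 17 MLL fusion targets, 8 were lower and 9 not past the threshold, with 10 lower when adjusted over the list alone (limma camera adjusted p = 2.3e-09; adjusted p = 0.301 with an estimated correlation). The 8 became 4 without I-BET replicate 2, 5 without combination replicate 1 and 3 without combination replicate 2. Of 21 cholesterol synthesis genes, 7 were lower and 14 not past the threshold, with 15 lower when adjusted over the list alone (limma camera adjusted p = 3.6e-12; adjusted p = 0.301 with an estimated correlation). The 7 became 3 without either I-BET replicate, 4 without combination replicate 1 and 1 without combination replicate 2. Of 14 MHC class II genes, 5 were higher and 9 not past the threshold, with 7 higher when adjusted over the list alone (limma camera adjusted p = 2.4e-09; adjusted p = 0.333 with an estimated correlation). The 5 became 3 without I-BET replicate 1 and 2 without I-BET replicate 2 or either combination replicate. Of 9 granule genes, 5 were higher, also 5 when adjusted over the list alone (limma camera adjusted p = 3.2e-05; adjusted p = 0.332 with an estimated correlation), with 2 without either I-BET replicate, 3 without combination replicate 1 and 1 without combination replicate 2. The neutrophil elastase gene ELANE rose by 1.15 ± 0.15 (limma adjusted p = 9.8e-04). Of 83 ribosomal protein genes, 2 were higher and 81 not past the threshold, with 46 higher when adjusted over the list alone (median 0.38, limma camera adjusted p = 7.2e-23; adjusted p = 0.54 with an estimated correlation). The count was 15 or 14 without SGC0946 replicate 1 or 2. Those 2 became 0 without either I-BET replicate or combination replicate 2, and 1 without combination replicate 1.

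Of 39 MYC and ribosome biogenesis genes, 3 were higher in the combination than with I-BET alone, or 6 when adjusted over the list alone (median 0.17, limma camera adjusted p = 6.6e-05; adjusted p = 0.576 with an estimated correlation). The count was 0 without either I-BET or combination replicate. Limma camera also ranked downward the lists of heat shock and unfolded protein response, immediate early genes, CDK inhibitors and p53 targets, haematopoietic transcription factors, and BET proteins and P-TEFb control (adjusted p from 5.0e-09 to 0.0162; adjusted p from 0.301 to 0.63 with an estimated correlation). The transcription factor result ended without I-BET replicate 1 (0.0893) or combination replicate 2 (0.203). The BET and P-TEFb result ended without I-BET replicate 2 (0.0696) or combination replicate 1 (0.0514). The snoRNA host list was ranked upward (limma camera adjusted p = 0.0216; adjusted p = 0.663 with an estimated correlation). This ended without I-BET replicate 1 (0.573) or combination replicate 1 (0.121). The histone (limma camera adjusted p = 0.107), mitochondrially encoded (median 0.09, limma camera adjusted p = 0.486) and cell cycle lists (median 0.02, limma camera adjusted p = 0.626) were not called with all libraries. Limma camera at the preset correlation ranked the cell cycle list downward without I-BET replicate 2 (0.0449) or combination replicate 2 (0.00167), and the histone list without I-BET replicate 2 (8.3e-04). The NF-kB list did the same without I-BET replicate 2 (4.2e-05) or combination replicate 1 (0.0378), and the BCL2 family without I-BET replicate 2 (0.0458).

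What did adding I-BET to SGC0946 change? Against SGC0946 alone, the combination lowered MYC (-1.60 ± 0.20, limma adjusted p = 3.7e-05), BCL2 (-1.67 ± 0.10, limma adjusted p = 8.6e-08) and CDK6 (-0.72 ± 0.16, limma adjusted p = 0.00357), and raised HEXIM1 (1.76 ± 0.11, limma adjusted p = 8.6e-08), HOXA9 (0.65 ± 0.11, limma adjusted p = 4.9e-04) and HOXA10 (0.63 ± 0.14, limma adjusted p = 0.00284). SAT1 (2.58 ± 0.19), DPYSL3 (2.56 ± 0.18), CAPN5 (2.32 ± 0.25), RGS2 (2.31 ± 0.29) and PLXNA3 (2.21 ± 0.15) rose most, while CCR2 (-4.54 ± 0.33), MPEG1 (-3.57 ± 0.31), INHBA (-3.41 ± 0.18) and the chemokine gene CXCL8 (-3.22 ± 0.53) fell, with limma adjusted p from 4.6e-08 for INHBA to 4.1e-04 for CXCL8. Of 39 MYC and ribosome biogenesis genes, 33 were lower, or 36 when adjusted over the list alone (limma camera adjusted p = 5.9e-19; adjusted p = 0.301 with an estimated correlation). All 16 genes of the histone list were higher, also 16 when adjusted over the list alone (limma camera adjusted p = 4.4e-13, adjusted p = 0.332 with an estimated correlation). Of 9 granule genes, 8 were lower, or 9 when adjusted over the list alone (limma camera adjusted p = 3.3e-07; adjusted p = 0.301 with an estimated correlation). Limma camera also ranked downward the haematopoietic transcription factor and monocyte marker lists, and upward the cell cycle and the BET and P-TEFb lists (adjusted p from 0.00249 to 0.0374; adjusted p from 0.351 to 0.753 with an estimated correlation). The monocyte result ended without SGC0946 replicate 1 (0.0549), the cell cycle result without SGC0946 replicate 1 (0.184) or combination replicate 2 (0.28), and the BET and P-TEFb result without SGC0946 replicate 1 (0.126). Lists that passed only when a library was left out were immediate early genes, upward without DMSO replicate 1 (0.0148), DMSO replicate 2 (0.0125) or combination replicate 2 (0.0382), and MHC class II, downward without SGC0946 replicate 2 (0.00529). Ribosomal proteins passed upward without SGC0946 replicate 1 (3.6e-10) or combination replicate 1 (0.00228), and downward without SGC0946 replicate 2 (0.00442). Limma called 4037 genes, 1630 higher and 2407 lower, with 869 changed at least 2-fold, and edgeR called 4089 and DESeq2 2817. Limma called 1152 higher and 1587 lower without SGC0946 replicate 1, 1063 and 1886 without SGC0946 replicate 2, and 850 and 1610 without combination replicate 2. The 869 became 419 with a pseudocount of 2.

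How did the single compounds differ directly? With I-BET against SGC0946, MYC differed by -2.04 ± 0.20 (limma adjusted p = 2.2e-06), BCL2 by -1.09 ± 0.10 (limma adjusted p = 1.7e-06), HOXA9 by 1.55 ± 0.11 (limma adjusted p = 1.3e-07), HOXA10 by 1.62 ± 0.14 (limma adjusted p = 5.2e-07), MEIS1 by 0.77 ± 0.11 (limma adjusted p = 1.2e-04) and HEXIM1 by 1.91 ± 0.11 (limma adjusted p = 1.8e-08). The zinc-finger gene KLF2 (3.11 ± 0.51), SAT1 (2.80 ± 0.19), EGR1 (2.66 ± 0.48), SERTAD1 (2.60 ± 0.17) and MT2A (2.58 ± 0.20) were higher with I-BET, and CCR2 (-4.85 ± 0.33), MPEG1 (-3.95 ± 0.31), JAML (-3.84 ± 0.29) and the myeloid lectin gene CLEC12A (-3.51 ± 0.19) were lower, with limma adjusted p from 1.8e-08 for CLEC12A to 5.7e-04 for EGR1. Of 14 MHC class II genes, 11 were lower with I-BET, and 1 was higher and 12 lower when adjusted over the list alone (limma camera adjusted p = 5.8e-06; adjusted p = 0.443 with an estimated correlation). That list had 1 higher and 8 lower without SGC0946 replicate 1. All 9 granule genes were lower, also 9 when adjusted over the list alone (limma camera adjusted p = 4.8e-09; adjusted p = 0.301 with an estimated correlation). MPO differed by -2.44 ± 0.21 (limma adjusted p = 6.5e-07) and CSF1R by -2.72 ± 0.23 (limma adjusted p = 6.1e-07). Of 25 immediate early genes, 13 were higher, or 14 when adjusted over the list alone (limma camera adjusted p = 1.7e-04; adjusted p = 0.706 with an estimated correlation). In that list 0 were lower, a count of 2 without I-BET replicate 1 and of 1 without either combination replicate. Of 39 MYC and ribosome biogenesis genes, 36 were lower, or 37 when adjusted over the list alone (limma camera adjusted p = 1.8e-20; adjusted p = 0.301 with an estimated correlation). Of 16 histone genes, 15 were higher, also 15 when adjusted over the list alone (limma camera adjusted p = 2.0e-12; adjusted p = 0.332 with an estimated correlation). Limma camera also ranked upward the lists of CDK inhibitors and p53 targets, heat shock and unfolded protein response, BET proteins and P-TEFb control, cholesterol synthesis, cell cycle and MLL fusion targets, and downward those of ribosomal proteins, monocyte markers and snoRNA hosts (adjusted p from 2.8e-06 to 0.0418; adjusted p from 0.301 to 0.753 with an estimated correlation). Of these, the cell cycle result ended without I-BET replicate 1 (0.0977) or SGC0946 replicate 1 (0.126), and the MLL target result without I-BET replicate 2 (0.0926) or SGC0946 replicate 1 (0.0673). The ribosomal protein result ended without SGC0946 replicate 1 (0.268), the monocyte result without SGC0946 replicate 1 (0.0613) and the snoRNA host result without I-BET replicate 1 (0.0905). Limma called 4952 genes, 2068 higher and 2884 lower, with 1113 changed at least 2-fold, and edgeR called 4976 and DESeq2 3528. Limma called 1216 higher and 2223 lower without I-BET replicate 1, and 1318 and 1920 without SGC0946 replicate 1. The 1113 became 622 with a pseudocount of 2.

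**Figure D3:**
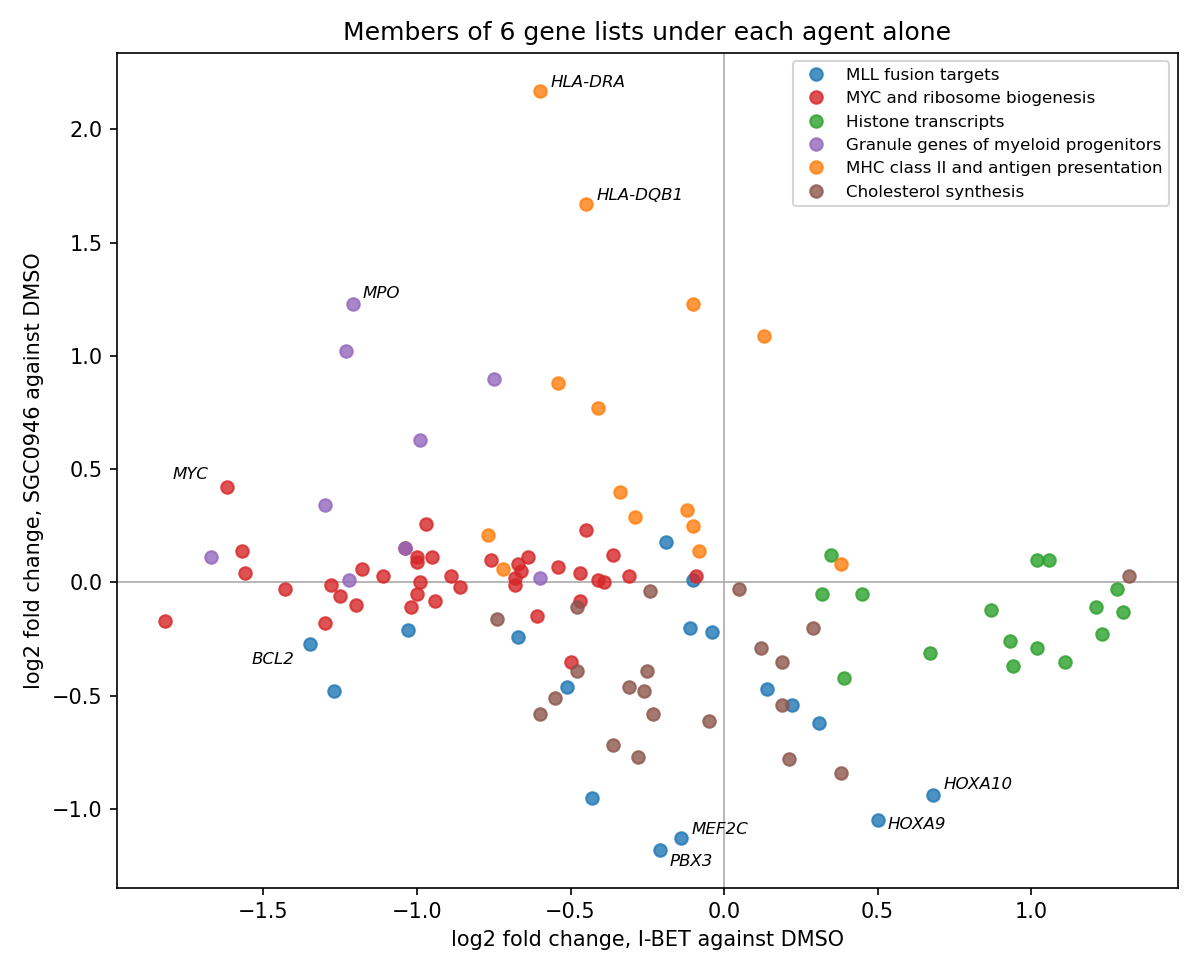
Log2 fold change with I-BET (x axis) against log2 fold change with SGC0946 (y axis), both relative to the same DMSO libraries, for members of 6 gene lists (colours). Each point is a gene, each value comes from n = 2 libraries per group, and no error bars are drawn; over all 16684 genes r = 0.127.

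Did the effect of a compound depend on the other? The interaction of HOXA9 was 0.15 ± 0.15 (limma adjusted p = 0.89), of MYC 0.02 ± 0.28 (limma adjusted p = 0.995), of BCL2 -0.32 ± 0.15 (limma adjusted p = 0.846) and of HEXIM1 0.01 ± 0.15 (limma adjusted p = 0.994), so none of these genes passed the test of a departure from additive log2 changes. Limma called 8 genes, 1 higher and 7 lower, with edgeR calling 2 and DESeq2 9, and 923 genes had an unadjusted limma p below 0.05. The count was 5 and 3 without DMSO replicate 1 or 2, 1 and 0 without I-BET replicate 1 or 2, 0 and 3 without SGC0946 replicate 1 or 2, and 2 and 0 without combination replicate 1 or 2. The cytokine receptor gene IL7R had the smallest adjusted p (interaction -2.04 ± 0.26, limma adjusted p = 0.0203), but was lost without I-BET replicate 2 (0.0604), either SGC0946 replicate (0.139 and 0.0869) or either combination replicate (0.0681 and 0.199). No list had a member past the threshold with all libraries. The BCL2 family and NF-kB lists each had 1 lower without DMSO replicate 1, and the immediate early list 1 higher without DMSO replicate 2. The ribosomal protein list leaned upward (median 0.29, limma camera adjusted p = 6.4e-14; adjusted p = 0.63 with an estimated correlation) and that result ended without SGC0946 replicate 2 (0.112). The mitochondrially encoded list also leaned upward (median 0.29, limma camera adjusted p = 4.3e-04; adjusted p = 0.606 with an estimated correlation). No single library ended that result.

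More interaction lists were called, and each of them ended without some library. The MYC and ribosome biogenesis list leaned upward (median 0.16, limma camera adjusted p = 3.9e-04; adjusted p = 0.615 with an estimated correlation). This ended without DMSO replicate 2 (0.1), I-BET replicate 1 (0.0816) or combination replicate 1 (0.0514). The cell cycle list did so too (median 0.12, limma camera adjusted p = 0.00506; adjusted p = 0.753 with an estimated correlation), and ended without DMSO replicate 1 (0.383), I-BET replicate 2 (0.301), SGC0946 replicate 1 (0.642) or combination replicate 2 (0.671). The MLL fusion target list (median 0.07, limma camera adjusted p = 0.0141; adjusted p = 0.547 with an estimated correlation) ended without I-BET replicate 1 (0.147), SGC0946 replicate 1 (0.238) or combination replicate 1 (0.0992). The monocyte marker list leaned downward (median -0.25, limma camera adjusted p = 0.0464; adjusted p = 0.753 with an estimated correlation). This ended without DMSO replicate 2 (0.817), I-BET replicate 1 (0.503), SGC0946 replicate 1 (0.747) or combination replicate 2 (0.218). Other lists passed only when a library was left out. Immediate early genes ranked downward without DMSO replicate 1 (0.00112) but upward without DMSO replicate 2 (1.4e-11), I-BET replicate 1 (6.0e-04) or combination replicate 2 (0.0309). NF-kB and cytokines ranked downward without DMSO replicate 1 (0.0127) or I-BET replicate 2 (0.00827) but upward without DMSO replicate 2 (0.0441) or I-BET replicate 1 (0.0398). Histones ranked upward without DMSO replicate 2 (0.00273) or I-BET replicate 1 (0.0203), and MHC class II without SGC0946 replicate 1 (0.0487). Cholesterol synthesis ranked downward without DMSO replicate 2 (0.0348), and heat shock and unfolded protein response without DMSO replicate 1 (0.03).

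Across 16684 genes, the I-BET effect without SGC0946 correlated with the I-BET effect with it (r = 0.826, slope 0.81), and the SGC0946 effect without I-BET with that in its presence (r = 0.537, slope 0.48); these pairs share no library. With the replicate 1 or replicate 2 libraries alone, r was 0.785 or 0.651 for the I-BET effect and 0.539 or 0.211 for the SGC0946 effect. Noise in the measured effects lowers r and pulls a slope below 1 even where the effect is the same, and was not corrected for. The slopes therefore do not show that 1 compound weakened the effect of the other. The I-BET and SGC0946 effects, which share both DMSO libraries, had r = 0.127, a covariance of 0.0192 and the same sign in 58.3% of genes. Simulations with no effect of either compound gave r = 0.497, a covariance of 0.0158 and the same sign in 66.6% from the shared controls alone. Those simulated changes held only noise, while the real ones also held effects, so the simulated r and share of same signs are no baseline. The covariances can be compared, and 0.0158 of the observed 0.0192 could come from the shared controls. The correlation of I-BET and SGC0946 effects was 0.104 or 0.268 with the replicate 1 or replicate 2 libraries alone, 0.225 without DMSO replicate 1, 0.215 without DMSO replicate 2 and 0.049 without SGC0946 replicate 2. Of the 416 genes lower with SGC0946, 193 such as FCER2 and OCSTAMP were also lower with I-BET (67.3 expected for independent calls) and 22 higher (49.1 expected). Of the 409 higher, 134 such as CCR2 were lower with I-BET (66.2 expected) and 83 higher (48.3 expected). A split chosen after seeing the data gave I-BET and SGC0946 a DMSO library each. The correlation of I-BET and SGC0946 effects was then 0.010 with DMSO replicate 1 for I-BET and 0.000 with DMSO replicate 2 for I-BET, with the same sign in 53.4% and 50.9% of genes. Genes lower with both compounds then numbered 49 (15.4 expected) and 85 (30.7 expected), and genes higher with SGC0946 and lower with I-BET 89 (30.3 expected) and 68 (21.7 expected). Genes higher with both numbered 40 (16.8 expected) and 29 (16.4 expected), and genes lower with SGC0946 and higher with I-BET 6 (8.6 expected) and 31 (23.3 expected). The expected counts take every gene as equally likely to be called, so they are too low if some genes are called more readily in both comparisons. An excess over them is therefore not by itself a shared or opposed effect. Genes are not independent replicates, so no p-value is attached to these correlations.

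Markers of other cell types were sparse in the table. The erythroid list had 1 member tested (EPOR, 0.33 ± 0.20 with I-BET, limma adjusted p = 0.233), which passed without DMSO replicate 1. The B lymphoid list had 2, with 0 past the threshold against DMSO in any group, and 1 higher with I-BET without I-BET replicate 2. The megakaryocyte list had 3 members, 2 of them higher with I-BET, 0 with SGC0946 and 1 with the combination. The I-BET count became 1 without either DMSO replicate and 0 without I-BET replicate 2, where TUBB1 and GP1BA had limma adjusted p of 0.109 and 0.105. The combination count became 0 without DMSO replicate 2 (GP1BA, limma adjusted p = 0.0807) and 2 without either SGC0946 replicate. TUBB1, with 65 reads in DMSO, shares 34% of its exons with ATP5F1E on the opposite strand, which had 1593. The T and NK list had 4 members, 2 of them lower with I-BET, 0 with SGC0946 and 2 with the combination. Of these, CD4 was lost with I-BET without DMSO replicate 2 (limma adjusted p = 0.0609) or I-BET replicate 2 (0.169), which left 1. In the combination CD4 was lost without DMSO replicate 1 (limma adjusted p = 0.109), DMSO replicate 2 (0.133) or combination replicate 1 (0.237), which also left 1. NKG7 changed by -0.88 ± 0.20 with I-BET (limma adjusted p = 0.0033). The epithelial and fibroblast list had 3 members, 0 of them past the threshold in any comparison.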

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

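Of the tests in this part, those of selection, of low values and of combination replicate 2 were chosen only after the result was seen. The interaction called 8 genes with limma, each departing from additive log2 changes. The interaction log2 changes were SERPINB2 -2.80 ± 0.46 (limma adjusted p = 0.0492), GAPT -2.39 ± 0.37 (limma adjusted p = 0.045), IL7R -2.04 ± 0.26 (limma adjusted p = 0.0203), FOXA1 -1.90 ± 0.32 (limma adjusted p = 0.0492), NAV3 -1.27 ± 0.21 (limma adjusted p = 0.0492), SESN3 -1.23 ± 0.18 (limma adjusted p = 0.0398), TENT5C -1.03 ± 0.17 (limma adjusted p = 0.0492) and UNC5C 1.08 ± 0.17 (limma adjusted p = 0.045). SERPINB2 had 0 reads in the I-BET libraries and 2 in the combination, and GAPT 3 and 26, so their interaction values rest on the pseudocount. IL7R rose from 3.22 and 2.70 in DMSO to 15.2 and 15.7 with SGC0946, and stood at 1.94 and 2.06 in the combination. The guidance gene UNC5C changed by -0.55 ± 0.12 with SGC0946 alone and by 0.52 ± 0.12 with SGC0946 on I-BET (limma adjusted p = 0.0129 and 0.0282). Every one of these calls was lost without I-BET replicate 2, SGC0946 replicate 1 or combination replicate 2, where 0 genes were called (726, 1416 and 502 genes with an unadjusted p below 0.05).

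Genes raised by SGC0946 tended to rise less when I-BET was present, but not by more than the spread between libraries. Genes chosen on the average of both SGC0946 changes, a choice independent of their difference when spreads are equal, had a mean interaction of -0.37 (33 genes, SE 0.24 over libraries, 95% interval -1.03 to 0.28). With genes chosen on 1 replicate and measured on the other, raised genes kept 0.74 and 0.65 of their SGC0946 change with I-BET. Lowered genes kept 1.02 and 0.84. Each of these ratios rests on 1 library per group, and their spread between libraries was not measured. Selection of chance-high genes therefore remains open. Compression of low values by the pseudocount (-0.33, SE 0.19, 8 genes with a mean of at least 20) and combination replicate 2 (-0.40 without it, SE 0.38, 37 genes) may contribute and remain open too. A need for BET proteins when genes such as IL7R are switched on after DOT1L inhibition remains a hypothesis that BET-protein occupancy at these genes would test, and genes lowered by SGC0946 had a mean interaction of 0.00 (SE 0.42, 27 genes).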

How the results depend on the processing

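With 2 libraries per group, a group reduced to a lone library is assumed to vary like the other groups, and the labels do not say whether replicates were separate cultures. No named-gene call was reversed: of 9489 alternative values for 507 results, 8862 stayed the same, 603 were weaker and 24 stronger; 42 changed sign, none of them called in either setting. The 8862 include 507 values without a filter, which equal the main ones because the filter removed 0 genes. They also include results past the threshold in neither setting, so 8862 overstates how well calls held. Of 399 named results past the threshold, 260 held under every alternative. Removing the intensity trend took SGC0946 against DMSO from 825 to 405 calls, combination against I-BET from 471 to 152 and the interaction from 8 to 0 (983 unadjusted). The replicate block gave 742 for combination against I-BET and 15 for the interaction, and more calls in every comparison (4670 to 5145 for I-BET). The main fit had no block, because the labels do not say that replicate numbers mark a shared culture, batch or day. In a check for pairing, correlations between pairs of groups ran from -0.10 to 0.28, so whether replicates pair remains open. If they do, the shared spread stayed in the error of the main tests. The interaction count was 2 with a pseudocount of 0.1, 0 with a mean of at least 5 (597 unadjusted), 4 with median-of-ratios scaling and 2 with edgeR. DESeq2 called 3125 genes for I-BET against DMSO and 317 for combination against I-BET. Leave-one-out counts ran from 2984 to 4697 for I-BET, 320 to 812 for SGC0946 and 3238 to 4866 for the combination against DMSO, 104 to 498 for combination against I-BET, 2460 to 3949 for combination against SGC0946, 3238 to 4894 for I-BET against SGC0946, and 0 to 5 for the interaction. The cause was not tested for these counts. The correlation of I-BET and SGC0946 effects (0.127) was 0.010 with DMSO replicate 1 for I-BET and 2 for SGC0946, and 0.000 with DMSO replicate 2 for I-BET and 1 for SGC0946, settings that share no library. Genes changed at least 2-fold went from 878 to 1126 for I-BET with a pseudocount of 0.1 and to 429 with 2. The filter removed 0 genes, so dropping it moved nothing. Scaling moved the share of lower calls by less than 10 points (I-BET 57.8 to 52%) except for the interaction (87.5 to 75%, of 4 calls, with median-of-ratios scaling), while the share for SGC0946 went from 50.4% to 34.3% without the trend and 61.9% with DESeq2. Of 140 list tests, 67 were called, 0 with an estimated correlation and 41 with fry, which kept 32 of them, and 57 to 77 without a library; the leave-one-out list tests and the split of the DMSO libraries were chosen after seeing the data.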

Other observations

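Small nuclear RNA genes, the RNA parts of the spliceosome, were higher with I-BET, a pattern found after seeing the data among 6 annotation classes and 7 comparisons. Of 27 snRNA genes, 22 were higher and 1 lower with I-BET (median 0.92), 22 higher and 1 lower in the combination (median 0.91), and 0 past the threshold with SGC0946 (median 0.17). RNU4-1 rose by 1.29 ± 0.19 with I-BET (limma adjusted p = 1.3e-04) and RNU1-1 by 1.01 ± 0.23 (limma adjusted p = 0.00401), and copies of the same snRNA share reads. Of 32 snoRNA genes, 5 were higher and 2 lower with I-BET (median -0.11). A set of 21 short RNAs with a mean of at least 5 had a median of -0.26 (SE 0.16). That set was drawn from snoRNAs and other short RNA classes, so it is not separate from the 32 snoRNA genes. The long RNA NEAT1, the scaffold of paraspeckles, rose by 1.13 ± 0.13 with I-BET (limma adjusted p = 2.3e-05) and by 0.80 ± 0.13 in the combination (limma adjusted p = 3.8e-04).

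Of the tests in this part, those of a fall in total RNA and of scaling were chosen only after the result was seen. All 16 tested members of the histone list were higher with I-BET, and calls for the other histone genes are not given. Exonic length, GC content and level were excluded, because 440 matched genes had a median of -0.18 (SE 0.03) against 0.98 for the histones. Reads moving between near-identical histone genes were excluded, because the summed value over 40 histone genes was 2.01 times that of DMSO (5990 and 4544 against 3015 and 2235). A fall in total labelled RNA could give the same picture and remains open, because the normalization sets the median change of all genes (0.005) near 0. A rise in transcription of histone genes, H4C8 among them, remains a hypothesis that a spike-in control would test.

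HOXA9 and HOXA10 were higher with I-BET and lower with SGC0946. Reads assigned to overlapping genes of the table amounted to 4.8% of those of HOXA9 and HOXA10 in DMSO. So low a share argues against those genes as the source. Antisense or read-through reads counted within HOXA9 and HOXA10, and overlapping genes outside the table, were not measured. This explanation is therefore not excluded. Scaling between libraries remains open: the smallest absolute log2 change under other scalings was 0.50 (SE 0.11), but their factors of at most 0.039 log2 units could not have removed it, while a fall in total RNA with I-BET would raise relative values. A separate BET-dependent restraint on these genes may explain the rise with I-BET but remains a hypothesis, which BET-protein occupancy at HOXA9 and HOXA10 with a spike-in control would test. The HOXA9 rise (0.50) was lost without DMSO replicate 2 (0.40, limma adjusted p = 0.0563).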
